A study of Mus musculus with 3 samples.

How the data were processed

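Spleen B cells of 6 mice, 3 LDHA-sufficient and 3 LDHA-deficient, were stained with antibody hashtags against CD45 and MHC class I, sorted for viable B cells and on GL7, and pooled on 1 lane of a 10x 5′ immune profiling kit, per the labels' protocols. The 3 libraries made from this lane hold transcripts, hashtags and heavy chains. The labels assign 6 hashtags, 3 to each genotype, and each hashtag stands for 1 mouse. Hashtag numbers name mice and pair none of them. The cell type given in the labels of the hashtag and heavy chain libraries is HSPCs, which conflicts with the protocols, and the cells were treated as B cells.

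The authors deposited gene expression as UMI counts per gene and barcode, a filtered matrix of 2836 barcodes, 32285 genes and 18170115 UMIs, and hashtags as UMI counts for 2831 barcodes. Cell Ranger 6.0.0, Seurat 4.2.1 and the mm10 build are named in the submitters' processing notes, and the header of the gene count file names Cell Ranger 6.0.2. The labels state a target of about 30000 cells. Heavy chains were deposited as 2241 contigs of 2014 barcodes with V, D and J genes, a clone number and, as a fraction, the V identity to germline (per the file headers). The clone number and the junction length are other values of that table. The tool and settings that called the clones are not given in the sources used here.

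Hashtags were called with HTODemux (Seurat 5.3.0, positive quantile 0.99) on the deposited hashtag counts. Of the barcodes with hashtag counts, 1856 (65.6%) carried a single hashtag, 820 (29.0%) hashtags of more than 1 mouse and 155 (5.48%) none. Hashtag doublets were removed, and from their rate about 164.5 of the single-hashtag barcodes (8.90%) are expected to hold 2 cells of 1 mouse. Scrublet called 0 of them, so it moved nothing. As an alternative chosen after seeing the data, as many barcodes with the highest Scrublet scores were removed. Cells with 500 or more genes, 1000 or more UMIs and under 10% mitochondrial UMIs were kept, 1849 in all, with median UMIs per cell of 4247, 4362.5 and 3904 in the LDHA-sufficient and 3712, 3786 and 3735 in the LDHA-deficient mice.

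Cells were clustered with the Leiden method (scanpy 1.11.5, igraph 0.11.9, resolution 0.8, 20 neighbours, 30 principal components, 2000 variable genes), with Ldha, antibody and T cell receptor segments, mitochondrial, ribosomal and sex-linked genes left out. A cluster was named when at least 3 fixed markers of a cell type were at least 1.5-fold above the other cells and detected in at least 10% of its cells. The names are rebuilt from markers and can differ from those of the study. The classes were GC B-like, activated or pre-GC B-like, follicular, marginal zone, interferon-responding and plasma cell-like cells, and 47 myeloid and plasmacytoid dendritic cells left out of every comparison, while 485 and 102 B cells of 2 clusters stayed unnamed and count among non-GC B cells. Non-GC B cells are B-lineage cells outside GC B-like and plasma cell-like clusters.

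UMI counts were summed per mouse and class, and LDHA-deficient was compared with LDHA-sufficient by the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, TMM, filterByExpr, robust, Benjamini-Hochberg adjusted p under 0.05), with a minimum of 20 cells per mouse. GC B-like cells and the test of the difference between the effects in GC B-like and non-GC B cells, with the mouse as a block, needed a minimum of 5 cells, chosen after seeing the data. DESeq2 1.42.0 was the alternative test. The fit was tried on simulated counts of the same depth with 200 changed genes. It recovered 73% of genes changed by a log2 of 1 and 95% of those changed by 2 over all B cells (9045 genes). The shares were 77% and 93% in non-GC B (8402 genes), 53% and 90% in activated B-like (4099 genes) and 60% and 94% in GC B-like cells (2754 genes). False calls were 16 of 184, 15 of 185, 11 of 154 and 6 of 160 in the same order. Genes were drawn independently, so shifts in cell state were not simulated.

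The genes named are Ldha, the 10 largest rises and falls among genes past the threshold whose genotypes do not overlap (antibody and receptor segments, sex-linked genes and clone IDs left out), for each list the 4 members with the smallest p, and Ldhb, Ldhc, Ldhd, Slc16a1, Slc16a3, Bcl6, Myc and Mki67, and 1 further gene that is not reported here. The 28 gene lists are glycolysis, HIF-1 targets and MYC targets (each without Ldha), TCA cycle, nuclear oxidative phosphorylation, mitochondrially encoded genes, NADH shuttles, serine and one-carbon metabolism, integrated stress response, unfolded protein response, cholesterol synthesis, S phase, G2 and M phase, p53 targets, genes induced by the antigen receptor and CD40, MHC class II, interferon response, hypermutation and class switch, dissociation stress, ribosomal proteins, markers of red, myeloid, T and NK cells, and markers of follicular, marginal zone, GC, dark zone, light zone, memory B and plasma cells. Lists were tested with camera (limma 3.58.1, correlation 0.01), with an estimated correlation and fry as alternatives, adjusted over the lists of a class. The design, classes, markers, lists, naming rule and most alternatives were fixed before the data were examined. Coordinates are from GENCODE M21 on GRCm38, the assembly that mm10 names.

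Shares and medians per mouse were compared by exact two-sided permutation tests over the 20 assignments of 6 mice, which cannot give a p under 0.1, so that none of these comparisons can pass 0.05. Intervals for shares are exact Clopper-Pearson intervals at 95% and cover counting error only. Shares of cells with a UMI were computed after thinning each cell to 2000 UMIs. For each barcode the heavy chain contig with the most UMIs was used (227 barcodes had 2). V mutation is 100 times (1 - V identity), a cell is switched when its constant region is neither IgM nor IgD, and GC B-like and non-GC B cells of a mouse were compared by an exact sign-flip test.

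Alternatives were DESeq2 size factors, no filter on low counts, antibody and receptor genes left out, equal cells per mouse, each mouse left out, hashtags called by a ratio of 3 with at least 20 UMIs, a stricter filter (1000 genes, 5% mitochondrial), Scrublet, resolutions of 0.4 and 1.2, cell cycle genes left out of the clustering, unthinned cells, genes in place of UMIs, contigs with 3 or more UMIs, cells with 2 or more V differences, and redefined clones. Chosen after seeing the data were clustering without activation genes, leaving out the barcodes of 1 IgA heavy chain shared by all mice, and a share of GC cells by markers without clusters. All mice share 1 lane, so no batch of lane or library separates them, and free RNA of the lane is shared between genotypes. Steps before pooling, such as staining and sorting, can still differ between mice. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.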

Results

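B cells from the spleens of 6 mice, LDHA-sufficient or LDHA-deficient (3 each), were profiled by droplet single-cell RNA sequencing. LDHA is the lactate dehydrogenase subunit that favours the conversion of pyruvate to lactate at the end of glycolysis. Cells of each mouse carried their own antibody hashtag, were sorted as viable B cells with a gate on GL7, a surface marker of activated and germinal centre (GC) B cells, and were pooled on 1 lane, so that transcripts, hashtags and immunoglobulin heavy chains were read from the same droplets. The mice are the replicates (n = 3 per genotype throughout). After the cell filter, 1849 cells with a single hashtag remained, 1802 of them of the B lineage. The LDHA-sufficient mice gave 323, 334 and 301 cells with 2263254, 2226047 and 1524675 UMIs, and the LDHA-deficient mice gave 285, 367 and 239 cells with 1345534, 1737899 and 1133366 UMIs. A heavy chain was found in 1169 of the B-lineage cells.

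Ldha was lower in every LDHA-deficient mouse than in every LDHA-sufficient mouse, in each of the 4 cell classes examined. Over all B cells it stood at 212.1 ± 39.9 CPM (UMIs scaled to TMM-adjusted library totals) in LDHA-sufficient mice and at 57.2 ± 11.4 in LDHA-deficient mice (mean ± SD, n = 3 each), a log2 fold change of -1.90 (SE 0.17, edgeR adjusted p = 0.000242). The log2 fold change was -1.58 in B cells outside the GC (169 ± 14.1 against 57.5 ± 15.8, adjusted p = 1.38e-11) and -2.16 in activated B-like cells (323 ± 41.7 against 72.5 ± 29.8, adjusted p = 3.49e-07). In GC B-like cells Ldha stood at 363.9 ± 84.7 against 85.5 ± 70.9, a log2 value of -2.19 (SE 0.41) that did not pass the adjusted threshold (adjusted p = 0.223). The LDHA-deficient values rest on 6, 11 and 2 UMIs. Ldha lies on chromosome 7 at 46841475 to 46855627 on the plus strand (GRCm38, ENSMUSG00000063229). The deleted part of the gene is not given in the sources used here, so the UMIs left in LDHA-deficient cells do not show whether an intact transcript is made.

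The other genes of lactate metabolism gave few UMIs. Ldhb, the other main lactate dehydrogenase subunit, gave 4 UMIs over all B cells of the 6 mice, Ldhd gave 4, and Ldhc gave 0, which allows up to 3. The lactate exporter Slc16a3 gave 3 UMIs. All 4 were below the expression filter. Ldhb gave 1, 0 and 1 UMIs in the LDHA-sufficient and 0, 1 and 1 in the LDHA-deficient mice. A rise of Ldhb transcripts as large as the fall of Ldha was thus not seen, and a small rise was not detectable at this depth. The lactate transporter Slc16a1 stood at 14.7 ± 0.644 CPM in LDHA-sufficient and 14.2 ± 5.45 in LDHA-deficient mice (log2 value -0.09, SE 0.30, adjusted p = 0.906).

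**Figure D1:**
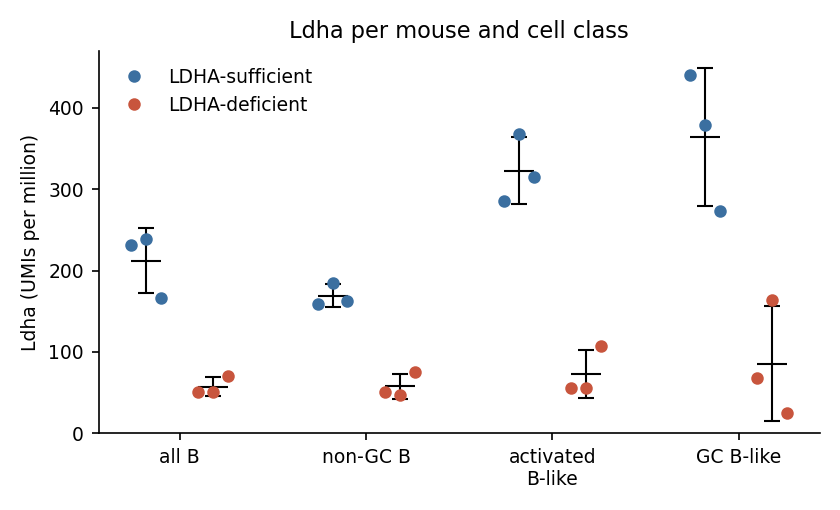
Ldha in CPM (vertical axis) in 4 classes of spleen B cells (horizontal axis), with each point 1 mouse and black marks the mean ± SD of 3 mice. Every LDHA-deficient mouse lies below every LDHA-sufficient mouse of its class, for example at 57.5 ± 15.8 against 169 ± 14.1 in non-GC B cells.

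GC B-like cells, which express Bcl6, S1pr2, Mef2b and Rgs13 and carry out affinity maturation, were scarcer in LDHA-deficient mice. They made up 18.2%, 23.2% and 5.69% of B-lineage cells in the LDHA-sufficient mice (58 of 319, 76 of 328 and 16 of 281) and 3.30%, 1.65% and 2.52% in the LDHA-deficient mice (9 of 273, 6 of 363 and 6 of 238). The means were 15.7% ± 9.00 and 2.49% ± 0.822, without overlap between the genotypes. LDHA-sufficient mouse 3 had far fewer GC B-like cells than the other LDHA-sufficient mice, and its 95% interval (exact Clopper-Pearson, 3.29% to 9.08%) overlapped those of LDHA-deficient mouse 1 (1.52% to 6.17%), mouse 2 (0.609% to 3.56%) and mouse 3 (0.931% to 5.41%). The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 mice allow. The labels do not say how the GL7 gates were pooled for each mouse, so the sort can set this share.

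Among the other B-lineage classes, follicular B-like cells (Fcer2a, Ighd, Ccr7) were 19.5% ± 4.08 in LDHA-sufficient and 26.7% ± 1.26 in LDHA-deficient mice, again without overlap. Marginal zone B-like cells (Cr2, Cd1d1, Dtx1, S1pr3) were 12.4% ± 3.72 and 13.6% ± 0.443, and interferon-responding B-like cells (Ifit1, Ifit3, Isg15) were 2.04% ± 0.749 and 2.44% ± 0.745. Plasma cell-like cells with Prdm1, Sdc1 and Tnfrsf17 were rare, at 8, 3 and 4 cells in LDHA-sufficient and 2, 0 and 1 cells in LDHA-deficient mice (1.62% ± 0.814 and 0.384% ± 0.368). The 2 unnamed clusters (24.8% ± 2.44 and 28.9% ± 3.31, and 7.06% ± 5.01 and 4.54% ± 0.640) and the other plasma cell-like cluster had exact permutation p of 0.2, 0.8 and 1. The exact permutation p was 0.1 for follicular and plasma cell-like cells, 0.7 for marginal zone and 0.6 for interferon-responding cells. After adjustment over the 9 clusters or classes tested, the smallest value was 0.225 by the same exact test. Shares sum to 100% within a mouse, so fewer GC B-like cells raise the others. Activated B-like cells are not compared by share, since the genes that define them differed between the genotypes, though their share is counted among the 9 in the adjustment.

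**Figure D2:**
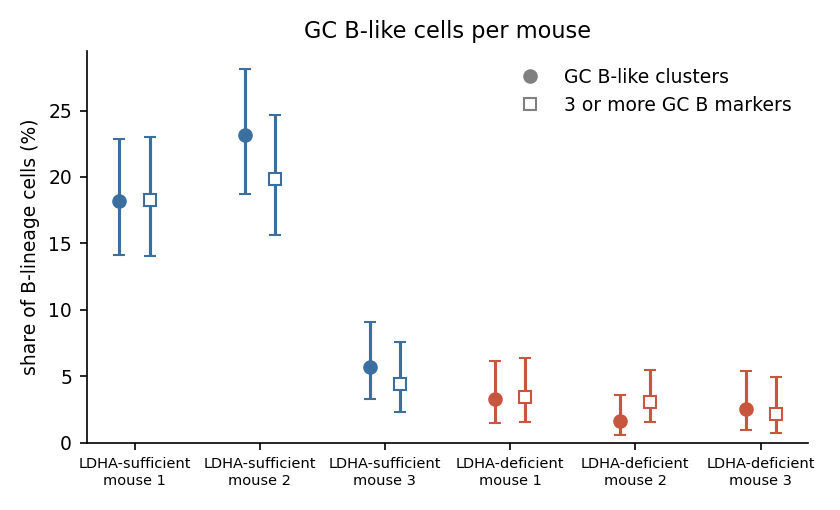
Share of B-lineage cells (vertical axis, %) for each of the 6 mice (horizontal axis). Filled circles are cells in GC B-like clusters, and open squares cells with UMIs of 3 or more GC B markers after thinning to 2000 UMIs. Bars are exact 95% binomial intervals that cover counting error only. The marker share was 4.07% in follicular B-like cells and 72.5% in GC B-like cells. The LDHA-deficient mice lie at 3.30%, 1.65% and 2.52% and the LDHA-sufficient mice at 18.2%, 23.2% and 5.69% by cluster.

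Over all B cells summed per mouse, mitotic genes such as Ccnb1 and Nek2 fell in LDHA-deficient mice, and the immediate early genes Egr3, Nr4a1 and Myc rose. Of 9183 genes tested, 112 passed the edgeR test, 19 higher and 93 lower. The largest falls (log2) were in Trerf1 (-3.72), Nt5e (-2.87), the surface enzyme CD73 that makes adenosine, C2cd2l (-2.60), the linker histone H1f0 (-2.25), the mitotic kinase Nek2 (-2.22), Ildr1 (-2.19), the centriole gene Stil (-2.06), the carbonic anhydrase gene Car13 (-2.01), the mitotic cyclin Ccnb1 (-1.96) and the heat shock gene Hspa2 (-1.95). The largest rises were in the immediate early transcription factor Nr4a1 (1.60), Arhgap18 (1.48), Psme2b (1.09), the actin-binding gene Cnn3 (0.99), the immediate early factor Egr3 (0.98), the urokinase receptor Plaur (0.96), Rasgef1b (0.91), the cannabinoid receptor Cnr2 (0.81), the complement receptor Cr2 (0.70) and the MYC antagonist Mxd4 (0.70). Psme2b is a close copy of Psme2, so its reads are uncertain. Cr2 stood at 496.9 ± 35.6 CPM in LDHA-sufficient and 807.7 ± 36.3 in LDHA-deficient mice (SE 0.10, adjusted p = 0.00496), and Trerf1 at 19.8 ± 7.02 and 1.62 ± 1.61 (SE 0.51, adjusted p = 0.00496). Myc rose by a log2 value of 0.67 (SE 0.14, adjusted p = 0.0316). The GC gene Bcl6 (-0.80, SE 0.21, adjusted p = 0.108) and the proliferation gene Mki67 (-1.58, SE 0.55, adjusted p = 0.277) had negative log2 values that did not pass.

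These sums mix cell states whose shares differed. In LDHA-sufficient mice, 93 of the 93 genes that fell were more abundant in GC B-like than in non-GC B cells, 47 of them by more than 5-fold, while 54.3% of all tested genes were more abundant in GC B-like cells. Of the 19 genes that rose, 17 were less abundant in GC B-like cells. Among non-GC B cells alone, 71 of the 93 were measured with a median log2 value of -0.18, against -1.09 for the same 71 over all B cells, and Ldha was the only one that passed there. The 19 genes that rose all had positive log2 values in non-GC B cells, with a median of 0.49 against 0.81 over all B cells. None of them passed there (edgeR, 0 of 19, with 441 of 8561 genes at an unadjusted p under 0.05 in that class and 1 gene called by DESeq2, Ldha). Of the 71 measured genes that fell, 56 had negative values there. Non-GC B cells were 742 of 928 LDHA-sufficient and 835 of 874 LDHA-deficient cells in the sums that picked these genes. A shared sign is thus partly built in.

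**Figure D3:**
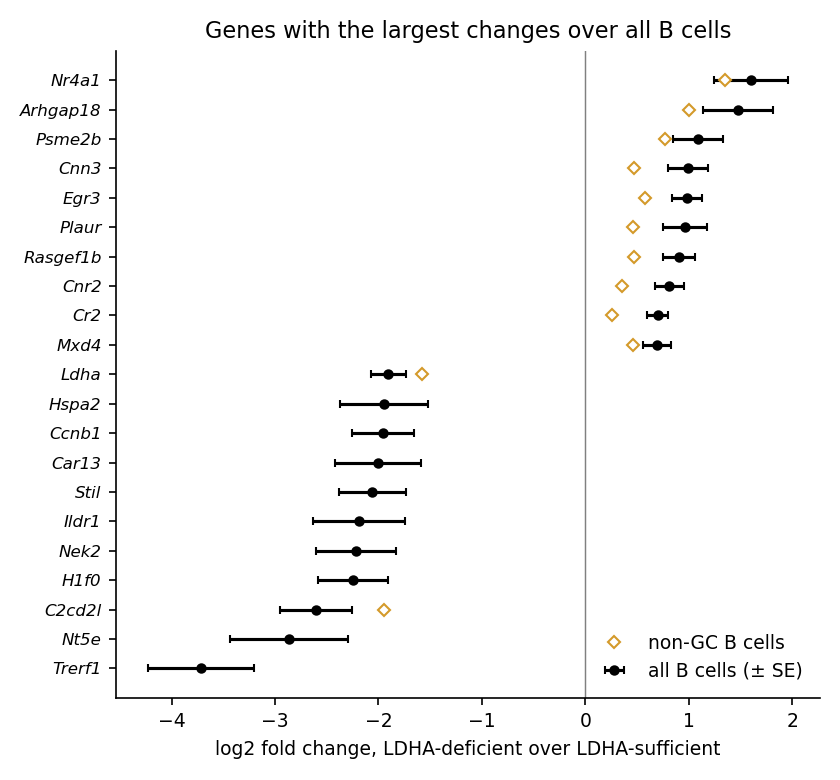
Log2 fold changes (horizontal axis, LDHA-deficient over LDHA-sufficient, n = 3 each) of the 10 genes with the largest rises, the 10 with the largest falls and Ldha over all B cells (black points ± SE), with the value in non-GC B cells where the gene was measured there (open diamonds). Cr2, for example, lies at 0.70 over all B cells, and Trerf1 at -3.72.

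The count of 112 genes rested on which mice entered. It was 35, 49 and 1406 without LDHA-sufficient mouse 1, 2 or 3, and 25, 6 and 4 without LDHA-deficient mouse 1, 2 or 3, and of the genes named for all B cells only Ldha passed in all 6 of these fits. With DESeq2, Myc, Mthfd2, Odc1, Rps27l, Arhgap18, Hspa2 and Psme2b lost their calls over all B cells. Values of the 2 genotypes did not overlap for 1804 of the 9183 genes (19.6%), against 10% by chance.

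By gene list, GC and mitotic genes had the medians furthest from 0 over all B cells. Camera called 15 of the 28 lists. None of these calls held when the correlation between genes was estimated (adjusted p = 0.461 to 0.485 with an estimated correlation). Of the 51 measured genes of the G2 and M phase, 19 fell and none rose (46 fell adjusted over the list alone; median log2 -1.30, camera adjusted p = 3.32e-48). Among them were Cdca2 (-1.90), Ckap2l (-1.71), Cks1b (-1.502) and Ube2c (-1.26). None of the 42 S phase genes passed over all genes (edgeR; 2 fell adjusted over the list alone), with a median of -0.93 (camera adjusted p = 1.24e-16). The 13 GC B markers had a median of -2.08 with none past the threshold over all genes, 11 falling and 1 rising adjusted over the list alone, and dark zone markers one of -1.57 with Cenpf (-1.47) and Ccnb1 called and 8 of 10 falling adjusted over the list alone (camera adjusted p = 2.53e-12 for both). Plasma cell markers had a median of -0.93, with Derl3 (-1.59) and Edem1 (-0.81), which serve protein quality control in the endoplasmic reticulum, called (6 fell and 1 rose adjusted over the list alone, camera adjusted p = 2.67e-06). Genes of hypermutation and class switch had a median of -0.40 (camera adjusted p = 0.00433) and p53 targets one of -0.40 (0.0107). The p53 call was lost without LDHA-sufficient mouse 1 (-0.20) or LDHA-deficient mouse 3 (-0.33). Genes induced by the antigen receptor and CD40 shifted up, with Egr3, Myc and Nr4a1 called among 23 and a median of 0.36 (11 rose and 1 fell adjusted over the list alone, camera adjusted p = 2.25e-06). Follicular B markers (0.35, camera adjusted p = 0.00141), interferon response genes (0.53, 6.96e-05) and MHC class II genes (0.26, 0.0141) also shifted up without a single gene called by edgeR over all genes. The MHC class II call was lost without LDHA-sufficient mouse 1 (0.17) or LDHA-deficient mouse 2 (0.18). The follicular median was 0.21 without LDHA-sufficient mouse 1 and 0.64 without LDHA-sufficient mouse 3, that of the induced genes 0.57 without LDHA-sufficient mouse 3, and that of interferon genes 0.34 without LDHA-deficient mouse 1. Within non-GC B cells, camera called none of the follicular (0.01, camera adjusted p = 0.993), interferon (0.16, 0.257) and MHC class II lists (0.03, 0.299). The induced and S phase lists were called there. Shifts over all B cells can thus reflect the shares of cell states in the sums.

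Among the metabolic lists, the 83 nuclear genes of oxidative phosphorylation had a median log2 value of -0.18 with none called by edgeR or adjusted over the list alone (camera adjusted p = 2.67e-06). Serine and one-carbon genes had a median of -0.50 (camera adjusted p = 9.7e-05), with the mitochondrial folate enzyme Mthfd2 (-1.04, adjusted p = 0.0401) called and 4 of 10 falling adjusted over the list alone. With 1 mouse left out Mthfd2 passed only without LDHA-sufficient mouse 3, and it also lost its call with DESeq2, ratio hashtag calls, clustering without activation genes and equal cells per mouse. The unfolded protein response (-0.38, camera adjusted p = 0.000289) and cholesterol synthesis (-0.28, 0.00481) had negative medians. All 4 calls were lost with an estimated correlation (adjusted p = 0.461 to 0.485 with an estimated correlation). Cholesterol synthesis also lost its call without LDHA-sufficient mouse 2 (-0.16), and had a median of -0.45 without LDHA-sufficient mouse 3 and -0.46 without LDHA-deficient mouse 2. Without LDHA-sufficient mouse 1 the median was -0.27 for serine and one-carbon genes and -0.25 for the unfolded protein response. Within non-GC B cells the medians were -0.05 for nuclear oxidative phosphorylation and -0.04 for serine and one-carbon genes. They were 0.04 for the unfolded protein response and 0.14 for cholesterol synthesis. None of the 4 lists was called there (camera adjusted p = 0.134 to 0.541). The shifts over all B cells can thus reflect the shares of cell states in the sums. Over all B cells, camera did not call glycolysis genes other than Ldha (14 genes, median -0.07, camera adjusted p = 0.281), though 4 of them fell adjusted over the list alone. Nor did it call HIF-1 targets (0.19, 11 of 12 with positive values, 0.115), the TCA cycle (-0.16, 17 of 21 negative, 0.0531) or mitochondrially encoded genes (0.08, 13 of 13 positive, 0.273), so a small shift in these lists is not excluded. Also not called were NADH shuttles (-0.15, 0.166), MYC targets (-0.06, 0.308, with Odc1 called at -0.62), the integrated stress response (-0.12, 0.175), dissociation stress genes (0.00, 0.784), ribosomal proteins (0.07, 0.259, with Rps27l called at -0.47), marginal zone markers (0.15, 0.342, with Cr2 called), light zone markers (0.24, 0.252) and memory B markers (0.35, 0.103, with Nt5e called). Red cell, myeloid, T and NK cell markers had a median of -1.15 over the 5 genes measured (0.291).

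Outside the GC, few genes differed. In non-GC B cells 5 of 8561 genes passed, all lower in LDHA-deficient mice: Ldha, Ly6k (log2 -1.498, SE 0.33, adjusted p = 0.0469), a gene of the Ly6 family of surface proteins, and the antibody V segments Igkv13-84, Ighv1-78 and Ighv10-3. The V segments lie outside the naming rule and were chosen after their values were seen. Ly6k lost its call without LDHA-sufficient mouse 1 or 3 or LDHA-deficient mouse 1 or 3, and in 9 of 15 other alternatives, DESeq2 among them. Myc had a log2 value of 0.51 (SE 0.14, adjusted p = 0.179) and Mki67 one of -0.36 (SE 0.37). Genes induced by the antigen receptor and CD40 shifted up (23 genes, median log2 0.30, none called by edgeR over all genes and 6 rising adjusted over the list alone, camera adjusted p = 3.67e-07; adjusted p = 0.701 with an estimated correlation), as did light zone markers (0.19, 0.00547). S phase genes (-0.17, 0.000231) and ribosomal proteins (-0.05, 0.00194) had negative medians, and none of the 4 calls held with the correlation estimated (adjusted p = 0.701 to 0.829 with an estimated correlation). The median of the induced genes was 0.17 without LDHA-deficient mouse 2, where the call was kept. The S phase median turned to 0.0565, 0.0646 and 0.0542 under 3 other clusterings (resolution 0.4, without activation genes and without the barcodes of a shared IgA chain), where light zone markers also lost their call and the induced genes had medians of 0.18, 0.14 and 0.18. Calls were also lost without LDHA-deficient mouse 2 (S phase, -0.04, and light zone, 0.11), LDHA-sufficient mouse 1 (light zone, 0.10) and LDHA-deficient mouse 3 (ribosomal proteins, -0.000967). The S phase median was -0.36 without LDHA-deficient mouse 3 and that of ribosomal proteins -0.09 without LDHA-deficient mouse 2. The number of genes called was 8, 13, 13 and 3 without LDHA-sufficient mouse 1, LDHA-deficient mouse 1, LDHA-deficient mouse 2 and LDHA-deficient mouse 3. The number of lists was 7, 10, 2 and 7 without LDHA-sufficient mouse 2, LDHA-sufficient mouse 3, LDHA-deficient mouse 2 and LDHA-deficient mouse 3. Red cell, myeloid, T and NK cell markers had a median of -2.36 over 4 genes (camera adjusted p = 0.126).

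Activated B-like cells, the class closest to the pre-GC cells of the labels, showed lower Ldha and higher Myc. Of 4274 genes, 7 passed (6 higher, 1 lower). Myc, the growth regulator induced when B cells enter the cycle, had a log2 fold change of 1.19 (SE 0.23; 105.2 ± 12 against 240.2 ± 24.2 CPM; adjusted p = 0.00736). The NF-kappaB inhibitor Nfkbid (1.42, SE 0.29, adjusted p = 0.0243), the adhesion receptor Cd44 (1.44, SE 0.31, adjusted p = 0.0341) and the activation marker Cd83 (0.84, SE 0.17, adjusted p = 0.0208) also rose, besides the V segments Igkv12-41 and Igkv17-121. Myc, Nfkbid and Cd83 are among the markers that name this class, so their values within it can depend on which cells were drawn into it. When activation genes were left out of the clustering, an alternative chosen after seeing the data, Myc rose by 1.35 (adjusted p = 0.0198) and Ldha fell by 2.20 (log2). Nfkbid (1.24, adjusted p = 0.446), Cd44 (1.12, adjusted p = 0.993) and Cd83 (0.57, adjusted p = 0.993) no longer passed in that setting, at log2 values within 1.5 times those above. With the stricter cell filter Cd44 was at 0.725 and Cd83 at 0.42, neither called. Over the alternatives Cd44 lost its call in 7 of 12, and Cd83 and Nfkbid in 5 of 12 each, DESeq2 among them. Among the 12, Scrublet calls and leaving the IgA barcodes out of the class gave the same values as the main fit, so they could lose no call. Ratio hashtag calls, resolution 0.4 and clustering without the IgA barcodes are not among them, since the class was absent or too small there. Over the alternatives the log2 value of Myc ranged from 0.48 to 1.35, and it lost its call in 5 of 12 of them (adjusted p from 0.000406 to 0.999), and without LDHA-sufficient mouse 3 (adjusted p = 0.0659) or LDHA-deficient mouse 2 (adjusted p = 0.109). Cd44 lost its call without LDHA-sufficient mouse 2 or 3 or LDHA-deficient mouse 2 or 3, Cd83 without any 1 LDHA-sufficient mouse or LDHA-deficient mouse 2, and Nfkbid without LDHA-sufficient mouse 1 or 2 or LDHA-deficient mouse 2. The number of genes called was 4, 4, 16 and 20 without LDHA-sufficient mouse 2, LDHA-sufficient mouse 3, LDHA-deficient mouse 1 and LDHA-deficient mouse 3.

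Genes induced by the antigen receptor and CD40 shifted up in activated B-like cells (median log2 0.52, 3 of 18 called and 7 rising adjusted over the list alone, camera adjusted p = 1.71e-15), as did light zone markers (0.60, 1 of 8 called and 3 rising adjusted over the list alone, 1.44e-06), and S phase genes had a negative median (-0.59, none of 28 called by edgeR and 3 falling adjusted over the list alone, 2.34e-13). Camera called 10 lists, and none held with an estimated correlation (adjusted p = 0.326 for the induced genes, 0.37 for light zone markers and 0.37 for S phase genes with an estimated correlation). The light zone call was also lost without LDHA-deficient mouse 2 (0.24, camera adjusted p = 0.0508) and with the stricter cell filter (0.40, 0.112). The S phase median was -0.37 without LDHA-deficient mouse 2 and -1.045 without LDHA-deficient mouse 3. Dissociation stress genes had a median of 0.48 in this class (5 genes, 3 with positive values and 1, the immediate early gene Junb at 1.203, rising adjusted over the list alone, camera adjusted p = 0.0434; adjusted p = 0.37 with an estimated correlation). Their shift has the same direction as that of Myc and the induced genes, so handling of the cells as a source of part of these rises is not excluded. Without activation genes in the clustering the stress median was 0.06 (camera adjusted p = 0.826), while Myc and the induced genes kept their calls. Ribosomal proteins (0.09, camera adjusted p = 4.45e-05) and MHC class II genes (0.14, 0.0444) also had positive medians. Mitochondrially encoded genes (-0.11, 0.0339), NADH shuttles (-0.31, 0.0339), G2 and M phase genes (-0.11, 0.0339) and interferon response genes (-0.29, 0.0481) had negative ones (adjusted p = 0.37 to 0.629 with an estimated correlation). Of these 7 lists, all but interferon (-0.715) lost their call without LDHA-deficient mouse 2 (stress 0.23, mitochondrially encoded -0.10, NADH shuttles -0.34, G2 and M phase -0.16, MHC class II 0.07, ribosomal proteins 0.04). Calls were also lost without LDHA-sufficient mouse 1 (stress 0.25, mitochondrially encoded -0.02, NADH shuttles -0.25, MHC class II 0.03, interferon -0.20) and LDHA-sufficient mouse 2 (stress 0.38, NADH shuttles -0.26, G2 and M phase -0.25, interferon -0.25). Further calls were lost without LDHA-sufficient mouse 3 (G2 and M phase -0.24, MHC class II 0.12), LDHA-deficient mouse 1 (mitochondrially encoded -0.10, NADH shuttles -0.34, G2 and M phase -0.09, interferon -0.09) and LDHA-deficient mouse 3 (interferon -0.22). Medians that kept their call moved to -0.45 for interferon and -0.17 for mitochondrially encoded genes without LDHA-sufficient mouse 3. The G2 and M phase median moved to -0.18 without LDHA-sufficient mouse 1 and -0.32 without LDHA-deficient mouse 3. The class joins a larger cluster with an S phase cluster led by Ccl22, Dtl and Hells, which held 9, 8 and 4 cells in LDHA-sufficient and 2, 3 and 8 in LDHA-deficient mice. With activation genes left out of the clustering the S phase median was -0.01 (camera adjusted p = 0.933). In that setting 2 lists passed, the induced genes among them (camera adjusted p = 1.55e-07). The number of lists was 5, 6, 6 and 3 without LDHA-sufficient mouse 1, LDHA-sufficient mouse 2, LDHA-deficient mouse 1 and LDHA-deficient mouse 2.

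In the GC B-like cells that LDHA-deficient mice did have, mitochondrially encoded transcripts were higher and GC markers lower as lists by camera, and no single gene passed. Neither list held with the correlation estimated (adjusted p = 0.0782 and 0.43 with an estimated correlation). Fewer than 20 such cells were found in each LDHA-deficient mouse, so the test planned before the data were examined could not be run, and a minimum of 5 cells per mouse was chosen after seeing the data. Of 2803 genes, edgeR called 0, with 214 at an unadjusted p under 0.05, and DESeq2 called 5. The smallest p-values belonged to Ldha, mt-Cytb, a subunit of respiratory complex III (log2 0.68, SE 0.14; 3995 ± 131 against 6392 ± 573 CPM; adjusted p = 0.223), and Laptm5 (-1.01, SE 0.22, adjusted p = 0.223). The 13 mitochondrially encoded genes had a median of 0.56 (13 rose adjusted over the list alone, camera adjusted p = 1.65e-15; adjusted p = 0.0782 with an estimated correlation). With the stricter cell filter that list was no longer called, at a median of 0.08. The light zone markers Il21r (-1.97), Cd83 (-1.40), Bcl2a1b (-1.14) and Nfkbia (-0.91) had a median of -1.27 (4 of 4 falling adjusted over the list alone, camera adjusted p = 6.65e-07; adjusted p = 0.0782 with an estimated correlation), and this list had positive medians of 0.37, 0.62 and 0.63 under 3 other clusterings. The GC B markers had a median of -0.95, with Basp1 at -2.68 (SE 0.55, adjusted p = 0.223; list camera adjusted p = 8.49e-09; adjusted p = 0.43 with an estimated correlation). That median was -0.53 without LDHA-deficient mouse 1 and -1.81 without LDHA-deficient mouse 2. Ribosomal proteins (0.20, camera adjusted p = 2.58e-08) and S phase genes (0.32, 0.000223) were higher, and the induced genes (-0.82, 0.00031) and MHC class II genes (-0.50, 0.000223) lower, with adjusted p from 0.146 to 0.65 with an estimated correlation. Under the same 3 clusterings the induced genes turned to 0.17, 0.38 and 0.25, the last 2 called in this opposite direction (camera adjusted p = 0.00027 and 0.00145). S phase genes lost their call there, and MHC class II genes at resolution 0.4 (-0.39, camera adjusted p = 0.0521). Calls were also lost without LDHA-deficient mouse 2 (induced genes, -0.45), LDHA-deficient mouse 1 (MHC class II, -0.19) and LDHA-sufficient mouse 3 (S phase, 0.09). The median of ribosomal proteins was 0.12 without LDHA-deficient mouse 1 and that of S phase genes 0.21 without LDHA-deficient mouse 3. The cycling cluster of the GC class, led by Top2a and Mki67, held 29 of 58, 32 of 76 and 12 of 16 cells in the LDHA-sufficient mice. In the LDHA-deficient mice it held 7 of 9, 4 of 6 and 4 of 6. The mix of clusters within the class thus differed between mice, with LDHA-sufficient mouse 3 inside the range of the LDHA-deficient mice. The count of genes was 1, 1, 5 and 3 without LDHA-sufficient mouse 1, 2 or 3 or LDHA-deficient mouse 2.

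The genotype effect itself was compared between GC B-like and non-GC B cells with the mouse as a block. Of 9013 genes, 10 differed, 5 in each direction. The activation marker Cd83 had log2 values of -1.40 in GC B-like and 0.38 in non-GC B cells (difference -1.95, SE 0.42, adjusted p = 0.0266), and the receptor for interleukin-21, Il21r, -1.97 and 0.24 (difference -2.32, SE 0.45, adjusted p = 0.00739). The lysosomal gene Laptm5 differed in the same sense (-1.24, SE 0.23, adjusted p = 0.0038), and mt-Cytb in the other (0.59, SE 0.13, adjusted p = 0.0371). The GC values rest on 6 to 9 cells in each LDHA-deficient mouse. Cd83 and Il21r are light zone markers, whose list median of -1.27 in GC B-like cells depended on the clustering. It was 0.37 at resolution 0.4, 0.62 without activation genes and 0.63 without the IgA barcodes. DESeq2 called 0 genes, while edgeR called 3 at resolution 0.4 and 16 without the IgA barcodes. The count was 21, 32, 75, 1 and 24 without LDHA-sufficient mouse 1, 2 or 3 or LDHA-deficient mouse 1 or 2.

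Cycling was common in GC B-like cells of both genotypes. After thinning to 2000 UMIs, 83.3% ± 2.96 of GC B-like cells in LDHA-sufficient mice and 85.2% ± 3.21 in LDHA-deficient mice held a UMI of Mki67, Top2a or Cdk1 (exact permutation p = 0.6), and 94.6% ± 4.79 and 100% ± 0 without thinning. The thinned difference of 1.88 percentage points was 0.0251 without LDHA-deficient mouse 1 and 0.223 without LDHA-sufficient mouse 2. It was 3.08 without LDHA-sufficient mouse 3 and 2.80 without LDHA-deficient mouse 2 or 3. Its direction reversed at resolution 0.4 (-1.72), without activation genes in the clustering (-6.30) and without the IgA barcodes (-6.54). In follicular B-like cells, which should be at rest, the thinned share was 24.9% (median 3152.5 UMIs, against 10252 in GC B-like cells), so the thinned shares of 18.3% ± 1.71 and 21.2% ± 1.71 in non-GC B cells (34.3% ± 1.501 and 33.6% ± 2.25 unthinned) are at background. Over all B cells the shares were 29.1% ± 6.64 and 23.6% ± 1.35 (exact permutation p = 0.4; 44.8% ± 6.28 and 36.0% ± 2.66 unthinned). The thinned difference of -5.47 was -2.61 without LDHA-sufficient mouse 2 and -9.12 without LDHA-sufficient mouse 3. Transcripts of the G2 and M phase list made up 0.401% ± 0.119 of UMIs over all B cells in LDHA-sufficient and 0.231% ± 0.0137 in LDHA-deficient mice, and those of the S phase list 0.206% ± 0.0594 and 0.127% ± 0.0101, without overlap (exact permutation p = 0.1 for each, the smallest possible). Within GC B-like cells the G2 and M share was 1.48% ± 0.0662 and 1.52% ± 0.128 (exact permutation p = 0.6). In activated B-like cells, a class that includes an S phase cluster, the S phase share was 0.234% ± 0.0270 and 0.150% ± 0.0371, without overlap (exact permutation p = 0.1). Thinning left out 28 LDHA-sufficient and 24 LDHA-deficient cells.

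The RNA content of cells differed most between classes. The median UMIs per cell over all B cells were 4141 ± 214 in LDHA-sufficient and 3767 ± 15.0 in LDHA-deficient mice, without overlap (exact permutation p = 0.1, the smallest possible). In non-GC B cells they were 3819 ± 47.2 and 3742 ± 22.0 (exact permutation p = 0.1), and in GC B-like cells 10289.5 ± 478 and 12306 ± 2325 (exact permutation p = 0.4). The GC difference of 2017 UMIs was 3351 without LDHA-deficient mouse 1 and 1222 without LDHA-deficient mouse 2. The non-GC difference of -76.8 was -50.8 without LDHA-sufficient mouse 3. Genes detected per non-GC B cell went the other way, at 1632 ± 34.5 and 1643 ± 20.7 (exact permutation p = 0.8).

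Heavy chains of GC B-like cells carried more V region differences from germline than those of non-GC B cells of the same mouse, in 6 of 6 mice. The within-mouse difference was 0.639 ± 0.460 differences per 100 bases (SD, n = 6), with p = 0.03125 by an exact sign-flip test, the smallest value 6 mice allow. GC B-like cells had 0.999 ± 0.387 differences per 100 bases in LDHA-sufficient mice (31, 53 and 11 cells) and 0.466 ± 0.346 in LDHA-deficient mice (5, 4 and 5 cells), which overlapped (exact permutation p = 0.2). In non-GC B cells the means were 0.107 ± 0.0580 and 0.0801 ± 0.0466 (exact permutation p = 0.6), and their difference reversed to 0.00531 without LDHA-sufficient mouse 3. Over all B cells they were 0.302 ± 0.0863 and 0.119 ± 0.0586, without overlap (exact permutation p = 0.1), and fewer GC B-like cells lower that mean.

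Class-switched heavy chains, those with a constant region other than IgM or IgD, made up a smaller share of all B, non-GC B and GC B-like cells in each LDHA-deficient mouse than in each LDHA-sufficient mouse. Among GC B-like cells 11 of 31, 15 of 53 and 1 of 11 were switched in the LDHA-sufficient mice (24.3% ± 13.6) and 0 of 5, 0 of 4 and 0 of 5 in the LDHA-deficient mice. These 0 counts allow shares of up to 52.2%, 60.2% and 52.2% (exact 95% limits). A difference was thus not detectable at this depth within GC B-like cells. The difference of -24.3 was -15.4 with ratio hashtag calls (exact permutation p = 0.3). In non-GC B cells the switched share was 3.32% ± 1.51 (5 of 165, 3 of 152 and 9 of 182) and 1.54% ± 0.208 (2 of 151, 4 of 230 and 2 of 128), and over all B cells 11.2% ± 2.06 and 4.43% ± 2.00, without overlap in either case (exact permutation p = 0.1 for each, the smallest possible). The non-GC difference of -1.77 was -0.960 without LDHA-sufficient mouse 3, -0.911 with the stricter cell filter (exact permutation p = 0.3) and -3.00 with activation genes left out of the clustering. It was -1.16 with ratio hashtag calls, -1.64 at resolution 1.2 and -1.71 without the IgA barcodes (exact permutation p = 0.2, 0.3 and 0.2). Over all B cells, 8 of the 22 switched cells of LDHA-deficient mice were non-GC B cells and 0 were GC B-like cells. The others lay in plasma cell-like clusters. In the larger of these 34 of 36 cells carried 1 IgA chain shared by all mice. Without the barcodes of that chain the all B difference was -6.44 in place of -6.82 (exact permutation p = 0.1). Fewer GC B-like cells also lower this share.

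Clones of 2 or more cells held 9.54% ± 4.12 of heavy-chain cells in LDHA-sufficient and 3.89% ± 2.52 in LDHA-deficient mice after each mouse was thinned to 140 cells (exact permutation p = 0.3). Of the 35 deposited clones with 2 or more cells, 18 held cells of more than 1 mouse, so a deposited clone is often not a true lineage. With clones defined by the same V gene, J gene and junction within a mouse the shares were 7.02% ± 1.88 and 3.04% ± 2.31 (exact permutation p = 0.2). Single-hashtag barcodes of the IgA chain shared by all mice, 1 to 9 per mouse, were not left out of these shares. They can count as an expanded clone under both definitions, so part of each share can come from that chain.

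**Figure D4:**
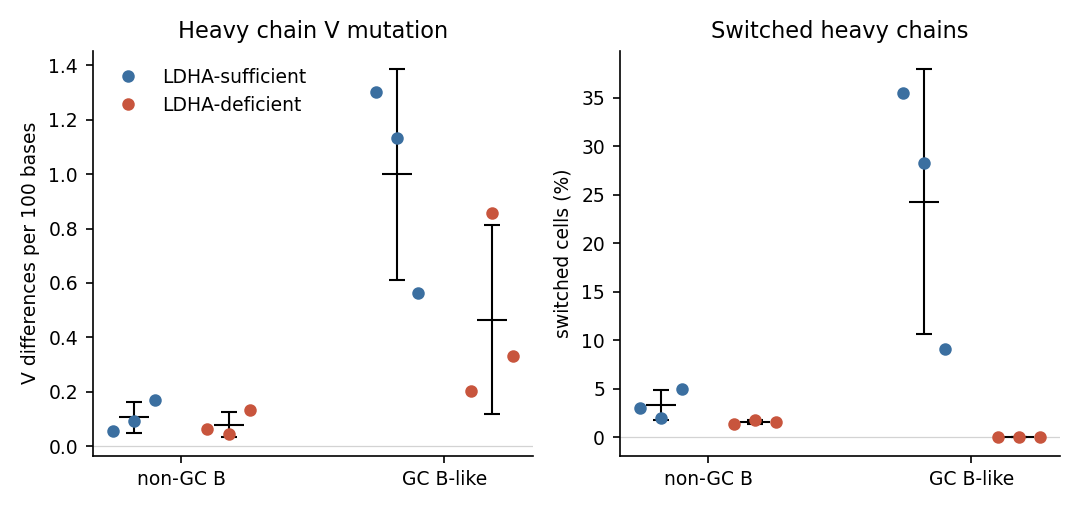
Heavy chain V region differences per 100 bases (left vertical axis) and share of cells with a switched constant region (right vertical axis, %) in non-GC B and GC B-like cells (horizontal axes), with each point 1 mouse and black marks the mean ± SD of 3 mice. GC B-like cells lie above non-GC B cells in V mutation in both genotypes, at 0.999 against 0.107 in LDHA-sufficient and 0.466 against 0.0801 in LDHA-deficient mice.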

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

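The minimum of 5 cells per mouse and all 3 tests on the shared IgA heavy chain were chosen only after the results were seen.

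The genotype effect differed between GC B-like and non-GC B cells for 10 genes, a count resting on 6 to 9 GC B-like cells in each LDHA-deficient mouse. The log2 differences were -5.01 for the V segment Igkv14-111, 2.57 for Fcrl5, -1.24 for Laptm5, -2.32 for Il21r, 2.62 for Aff1, 4.001 for Mfhas1, -1.95 for Cd83, 0.59 for mt-Cytb, 3.57 for Cd93 and -2.94 for Tmem64. Fcrl5 is a marker of marginal zone B cells. Igkv14-111 gave 304 UMIs in LDHA-sufficient and 2 in LDHA-deficient GC B-like cells, and Mfhas1 gave 6 and 11.

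One IgA heavy chain (IGHV1-42, IGHJ3) was read in 191 barcodes spread over all 6 mice, 37 with a single hashtag (1 to 9 per mouse) and 132 without one, which is 85.2% of the 155 hashtag-negative barcodes. Across the hashtag-negative barcodes of this chain abundant genes varied no more than counting noise (median chi-square per degree of freedom 1.00, against 3.89 across ordinary cells), which fits 1 pool of RNA spread over many droplets. Free RNA added to ordinary B cells was not supported, since the spread was also 1.02 across the single-hashtag barcodes, and neither was a clone expanded in 1 mouse, since the mouse with the most held 24.3% of them. These barcodes made up 34 of the 36 cells of a plasma cell-like cluster, with Jchain at 6610 CPM against 208.5 in other non-GC B cells. Mature B cell genes stood at a median of 0.796 of their level in other non-GC B cells (Ms4a1 0.776, Cd22 1.31), which plasma cell RNA alone would not bring, so the source of the pool stays open.

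Hashtags of 2 or more mice were found in 820 barcodes, which were left out of every genotype comparison and used only to weigh hashtag loss. After a B cell sort, 47 cells were myeloid or plasmacytoid dendritic cells.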

How the results depend on the processing

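Clustering without activation genes, removal of the shared IgA barcodes and of the highest Scrublet scores, and the minimum of 5 cells were chosen only after the results were seen.

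The fall of Ldha over all B cells and the direction of the GC B-like share held in every setting, while gene and list counts depended on the setting. The cause was not tested. For activated B-like cells ratio hashtag calls, resolution 0.4 and clustering without the IgA barcodes were not run, since the class was absent or had too few cells. The difference in cycling GC B-like cells turned to -1.72 at resolution 0.4, -6.30 without activation genes in the clustering and -6.54 without the IgA barcodes, that in non-GC B cells to -0.679 unthinned, and the difference in UMIs per non-GC B cell to 10.7 as genes detected. Genes changed over all B cells numbered 184 with DESeq2, 659 without the low-count filter, 194 without antibody genes and 70 without the highest Scrublet scores. In non-GC B cells they numbered 1 with DESeq2, 26 without the filter, 3 with ratio hashtag calls, 8 without the IgA barcodes, 3 without the highest Scrublet scores and 3 with equal cells. In activated B-like cells they numbered 3 with DESeq2, 22 without the filter, 1 with stricter cells, 1 without cell cycle genes and 3 with equal cells. In GC B-like cells they numbered 5 with DESeq2, 50 without the filter, 1 with ratio calls, 8 at resolution 0.4, 11 without activation genes, 10 without the IgA barcodes and 1 without the highest Scrublet scores. Interaction genes numbered 0 with DESeq2, 37 without the filter, 16 without antibody genes, 3 at resolution 0.4 and 16 without the IgA barcodes.

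Lists called numbered 0 with an estimated correlation in all 4 classes, and with fry 0 except for 3 in GC B-like cells. They numbered 7 in non-GC B cells with ratio calls, and in activated B-like cells 1 with stricter cells, 4 without cell cycle genes and 2 without activation genes. Medians reversed for S phase in non-GC B cells (0.0565 at resolution 0.4, 0.0646 without activation genes, 0.0542 without the IgA barcodes), in activated B-like cells for G2 and M phase (0.21 without activation genes), ribosomal proteins (-0.0435 without activation genes, -0.00249 with equal cells) and mitochondrially encoded genes (0.0260 with stricter cells), and in GC B-like cells for induced genes (0.17, 0.38 and 0.25) and light zone markers (0.37, 0.62 and 0.63) at resolution 0.4, without activation genes and without the IgA barcodes, where the last 2 induced-gene values passed. With all 6 mice, medians that kept their call but moved by over 1.5 times were, in non-GC B cells, those of induced genes under the same 3 clusterings (0.18, 0.14 and 0.18). In activated B-like cells they were those of induced genes (0.88), light zone markers (1.22), ribosomal proteins (0.24), MHC class II (0.21) and G2 and M phase genes (-0.40) at resolution 1.2, of S phase (-0.36) and G2 and M phase genes (-0.26) without cell cycle genes in the clustering, of G2 and M phase (-0.23) and dissociation stress genes (0.26) without the highest Scrublet scores, and of G2 and M phase genes (-0.21) with equal cells. In GC B-like cells they were those of induced genes (-0.39), MHC class II (-0.33) and S phase genes (0.05) with ratio calls, of MHC class II (-0.79) and ribosomal proteins (0.43) with stricter cells, of S phase genes (0.11) without cell cycle genes, and of MHC class II (-0.79), S phase (0.58) and mitochondrially encoded genes (0.36) with equal cells.

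With 1 mouse left out, genes changed ranged from 4 to 1406 over all B cells, 3 to 13 in non-GC B, 4 to 20 in activated and 0 to 5 in GC B-like cells, and 1 to 75 for the interaction. Lists ranged from 2 to 10 in non-GC B and 3 to 10 in activated B-like cells. The V mutation difference in non-GC B cells ranged from -0.0530 to 0.00531, reversed without LDHA-sufficient mouse 3, and that of GC against non-GC B cells from 0.518 to 0.738, where 5 mice cannot pass the exact test.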

Other observations

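The split tests of the gene counts in all B, non-GC B, activated B-like and GC B-like cells were chosen only after the results were seen, and the other tests in this part were set down before their own values were computed.

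GC clones were found mainly in LDHA-sufficient mice 1 and 2, the mice with the most GC B-like cells. Of 12 clones of 2 or more cells of 1 mouse with a GC B-like cell, 11 were in LDHA-sufficient mice and 1 in an LDHA-deficient mouse. GC B-like cells with a heavy chain numbered 95 and 14. LDHA-sufficient mouse 3 had no such clone, so genotype and the number of GC B-like cells cannot be told apart here. The largest held 5 GC B-like cells with IGHV1-26 in LDHA-sufficient mouse 2 (mean V mutation 0.748%), and a clone of 3 cells with IGHV1-49 had 1.81%. The largest B cell cluster, 485 cells led by Klf2, S100a10, Tsc22d3 and Vim, and a cluster of 102 cells led by Hivep3, Atp1b1 and Klhl14 matched no fixed marker list. LDHA-sufficient mouse 3 held 36 of these 102 cells and 15 of the 40 myeloid cells, and had the fewest GC B-like cells of its genotype.

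Fewer GC B-like cells in LDHA-deficient mice could come from cluster borders, hashtag calls or the sort. Counted without clusters, cells with 3 or more GC markers were 2.89% of B cells in LDHA-deficient and 14.2% in LDHA-sufficient mice (ratio 0.204). Such cells made up 72.5% of GC B-like and 4.07% of follicular B-like cells, so both shares mix GC cells with background. The ratio is thus not one of GC cells. Enough GC cells in other clusters to make up the difference were not supported, since they would raise the LDHA-deficient share well above 2.89%. A smaller number in other clusters is not excluded. GC cells lost to doublet calls were predicted to give LDHA-deficient pairs at least as high a share with 3 or more GC markers. That was not seen. Barcodes of 2 LDHA-deficient mice held 3 or more GC markers in 6.77% (13 of 192) and those of 2 LDHA-sufficient mice in 16.8% (17 of 101, ratio 0.402). This ratio is higher than the 0.204 of single-hashtag cells, and it counts barcodes rather than mice. A smaller loss to doublet calls is therefore not excluded. Why LDHA-deficient pairs were more numerous was not tested. Cells whose hashtag was too weak to be called are not covered by this comparison. Of the hashtag-negative barcodes, 23 lacked the IgA chain shared by all mice. GC B-like cells were also fewer relative to activated B-like cells (ratio 0.123), a class whose defining genes differed between the genotypes, and the labels do not say how GL7 gates were pooled, so the sort remains open. A hypothesis is a loss of GC B cells without LDHA, which counts of GL7-positive cells before pooling would test.

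Ldha transcripts remained in LDHA-deficient non-GC B cells at 33.3% of the LDHA-sufficient level. Free RNA, put at 16.3% of UMIs from 15 myeloid and red cell genes, would give 41.3% of the level measured in these LDHA-deficient cells, which leaves its part open. The spread of Ldha UMIs over these cells was 1.24 times counting noise. That lies inside the simulated range of 1.00 to 1.45 for a low level in all cells. It lies outside that of 1.60 to 2.98 for a minority with the full level and no Ldha in the other cells. Free RNA was not added to this minority and, spread evenly, would lower its range, so a minority on top of free RNA is not excluded. A hypothesis is a transcript made from the deleted gene, which reads over the deleted part would test.

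All 10 splits of the 6 mice into 3 and 3 were counted alike, and with so few splits none of these counts can be told from chance. Over all B cells 112 genes was the largest count in 1 of 10 splits (the next gave 21), and 3 splits gave 15 or more lists. In non-GC B cells 2 splits gave 5 or more genes and 5 gave 4 or more lists. In activated B-like cells 1 split gave 7 or more genes and 1 gave 10 or more lists. In GC B-like cells the gene count was 0, which all 10 splits reach by construction, so this comparison decides nothing, and 3 gave 7 or more lists. For the interaction 2 splits gave 10 or more genes, and the highest other, which set LDHA-sufficient mice 1 and 2 and LDHA-deficient mouse 2 apart, gave 52, so structure other than genotype reaches larger counts.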
